A study of Mus musculus with 6 samples.

How the data were processed

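RNA was measured in 6 libraries of cells taken from the brains of adult male mice carrying one Cx3cr1CreER allele and 2 floxed Csf1r alleles. CreER is a Cre recombinase that acts when tamoxifen is present, and a floxed gene is one that Cre can cut. Per the labels, the mice were 10 months old and received tamoxifen in their food for 12 weeks and then control food for 4 weeks. Cells were pulled down with magnetic beads against CD11b, a surface integrin of myeloid cells, and then sorted by flow cytometry on green fluorescent protein (GFP). Each group, GFP positive and GFP negative, had 3 libraries. The RNA was linearly amplified before library preparation, per the labels' protocols, and amplification can distort levels of scarce transcripts.

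The deposited table holds raw read counts per gene, whole numbers with no normalization, for the 6 libraries. FastQC, STAR and HTSeq and the genome build mm9 are named in the submitters' processing notes, without versions or settings. The strand setting of the counting is not given in the sources used here, so reads of overlapping and antisense genes cannot be separated. Genes with near-identical copies may share or lose reads, which makes Lyz1 and Lyz2, H2-Q6 and H2-Q7, Hspa1a and Hspa1b, the Ms4a family and the predicted Gm genes uncertain. The table lists 28087 Ensembl gene identifiers, each with at least 2 counts over the 6 libraries, and no line without a gene. Names for 27931 identifiers came from the GENCODE M21 annotation, which is built on another assembly, so it was used for names and gene types only and no coordinates are given. The remaining 156 identifiers had no match.

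Genes were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 17378 genes holding 99.79% of the counts. Libraries were scaled by TMM, and the factors ran from 0.966 to 1.03. Differences between groups were tested with the edgeR quasi-likelihood F test with group as the only term and Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Levels are given as TMM-scaled CPM (counts over the scaled library total), mean ± SD over 3 libraries, and log2 fold changes as GFP positive over GFP negative ± SE. Prior count was 2 for log2 CPM.

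Before the data were examined, 37 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule named Csf1r and Cx3cr1, then the 10 largest rises and the 10 largest falls among called genes with a mean of at least 10 CPM and no overlap between the groups. It also named the 4 members of each list with the smallest p, and the 2 most abundant members of lists that mark other cell types. Other genes in the text were chosen after their values were seen and are said to be so. Some genes are not reported here by name, although the counts of list members include them, and members named by the rule that did not pass are printed only in part. Lists with at least 5 tested members, 36 of them, were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Members were also counted with adjustment over the list alone. Lists overlap, so their counts are not independent.

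Library totals ran from 8570909 to 20536782 counts. A gene with 3 counts, the most that a true level could give when 0 are seen, corresponds to between 0.15 and 0.35 CPM. Intervals for shares of counts are 95% Wilson intervals and, like that floor, cover counting error only. The labels do not say that the samples came from separate mice, so the p-values measure the spread between these samples, which may be partly technical.

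The method was tested on simulated counts for this comparison, drawn over 16961 genes for single genes and 16975 for lists. It recovered 10 of 50 genes changed 2-fold, 49 of 50 changed 4-fold, 50 of 50 changed 8-fold and 50 of 50 changed 16-fold. The changed genes were drawn from those with a mean of at least 10 CPM. Of its 172 calls, 13 (7.56%) were false. A simulated list of 30 genes changed 2-fold was found by camera at adjusted p = 1.6e-33 with the preset correlation and adjusted p = 0.0032 with an estimated correlation, and 0 of 20 unchanged lists were called. The simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.84, for monocyte genes. The simulation therefore does not test whether the preset correlation gives false list calls in these data. A chi-square comparison of all 15 pairs of libraries found none within sampling noise, the lowest value being 16.4 per gene.

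The alternatives were DESeq2 size factors, upper-quartile scaling and library size alone in place of TMM, DESeq2 1.42.0 and limma-voom in place of the edgeR test, no filter and a stricter filter of 5 CPM in 3 libraries, the replicate number as a block, glmTreat against a 1.5-fold change, and leaving out each library in turn. Counts without GFP negative replicate 2 were added after that library was seen to stand apart. No library was left out of the reported values.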

Results

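The data are gene counts from CD11b-bead-isolated brain cells of mice with tamoxifen-inducible Cre and floxed Csf1r, sorted into GFP positive and GFP negative cells, with 3 libraries in each group. Microglia are the resident macrophages of the brain and depend on the receptor encoded by Csf1r. The series title sets the comparison in the question of how macrophages of peripheral origin that settle in the brain differ from microglia. The labels do not state which cells carried GFP. The GFP positive libraries held 19933686, 16086326 and 20536782 counts for replicates 1, 2 and 3, and the GFP negative libraries held 14848893, 8570909 and 11874463. Between 22433 and 23923 genes had at least 1 count in a library.

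Csf1r, the targeted gene, averaged 3597 ± 409 CPM in GFP positive and 5639 ± 1240 CPM in GFP negative libraries. Its libraries held 3180, 3997 and 3614 CPM with GFP and 4212, 6454 and 6250 CPM without it. The log2 fold change was -0.65 ± 0.18 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0515), which missed the threshold, although all 3 GFP positive libraries lay below all 3 GFP negative ones. The adjusted p was 0.0166 and 0.0351 without GFP negative replicates 1 and 2, and the other 4 fits that left out 1 library missed the threshold, with adjusted p = 0.158 without GFP negative replicate 3 and 0.208, 0.0813 and 0.154 without GFP positive replicates 1, 2 and 3. Cx3cr1, the fractalkine receptor gene that holds the Cre driver, averaged 1083 ± 171 against 1443 ± 564 CPM, a log2 fold change of -0.41 ± 0.26 (adjusted p = 0.361), and the groups overlapped. Gene-level counts sum reads over all exons, so they do not show whether a floxed part of Csf1r was removed. Of the 9 tested genes of the Csf1 receptor axis, 0 rose and 2 fell, Csf1, a ligand of the receptor, by 2.87 on the log2 scale and Csf3r, the G-CSF receptor, with a log2 fold change of -0.84. Adjusted over the list alone, 1 rose and 4 fell (list adjusted p = 0.067 with camera, and adjusted p = 0.66 with an estimated correlation). Without GFP negative replicate 2, 2 rose and 4 fell, and without any 1 of the other 5 libraries 0 rose and 1 to 3 fell.

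Several genes that mark microglia were far lower in GFP positive cells, and genes of peripheral and border macrophages were higher. Sall1, a transcription factor of microglial identity, was at 77.1 ± 30.1 CPM with GFP and 1684 ± 197 CPM without it, and Lyz2, the lysozyme gene of myeloid cells, was at 2821 ± 414 against 468 ± 365 CPM. Of 17378 genes tested, 1070 were higher and 1192 lower in GFP positive libraries, 2262 in all. At least 4-fold differences were found for 327 of the higher and 381 of the lower genes. The groups did not overlap for 5776 genes (33.2%), where chance gives 10%.

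The count of calls depended on which libraries were used. It was 4317 (2342 higher, 1975 lower) without GFP negative replicate 2, and 819, 1374 and 1030 without GFP positive replicates 1, 2 and 3, and 1354 and 1149 without GFP negative replicates 1 and 3. GFP negative replicate 2 stood apart. On the first principal component (56.6% of the variance) the GFP positive libraries lay at -70.2, -49.3 and -67.4, GFP negative replicates 1 and 3 at 82.8 and 92.5, and GFP negative replicate 2 at 11.5. The second component (23.8%) placed that library at -95, with the others between -2.76 and 32.6. It had the lowest total and the highest mitochondrial share of counts, 6.39% (95% Wilson interval 6.375 to 6.408%), against 3.59 to 5.06% in the other 5.

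**Figure D1:**
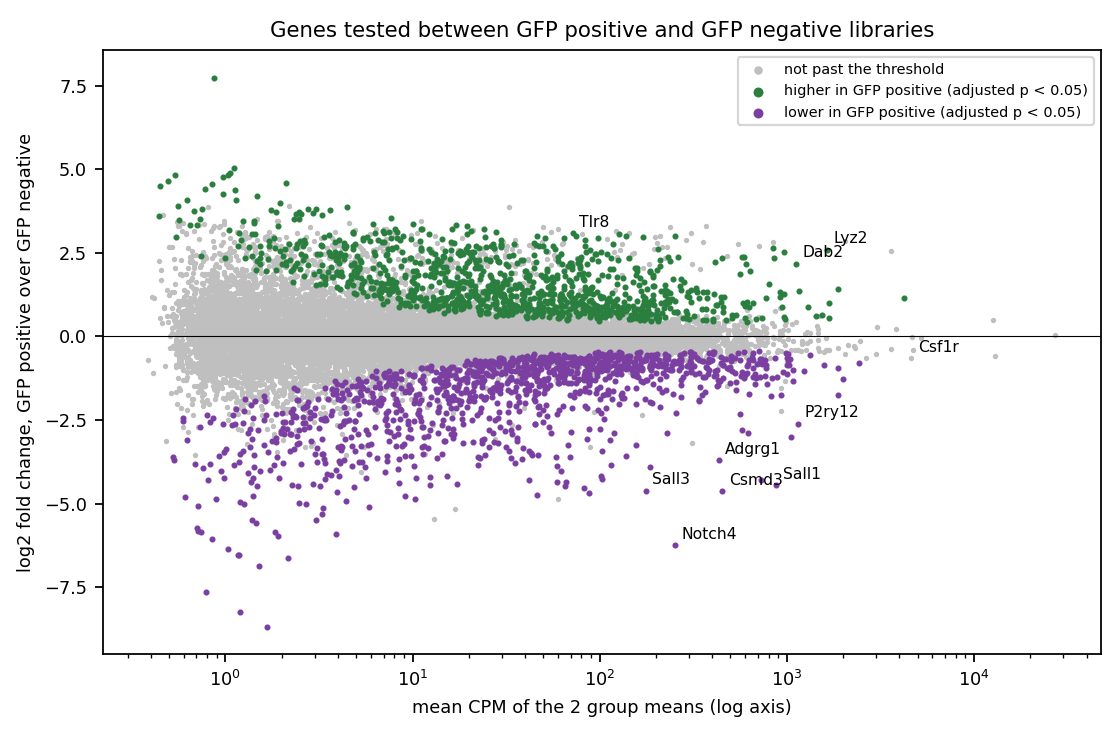
Each point is one of the 17378 genes tested, with the mean CPM of the group means on a log axis and the log2 fold change of GFP positive over GFP negative on the vertical axis. Colours mark the 1070 higher and 1192 lower genes, and Sall1 lies at -4.45 and Lyz2 at 2.59.

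The largest falls included microglial regulators and surface genes. Sall1 fell by 4.45 on the log2 scale (SE 0.29, adjusted p = 0.000205) and its relative Sall3 fell by 4.62 (13.7 ± 8.40 against 339 ± 123 CPM). Upk1b, a tetraspanin, fell by 4.67 (6.61 ± 2.37 against 169 ± 34.1 CPM), Csmd3, a large transmembrane protein gene, by 4.63 (35.0 ± 18.7 against 869 ± 386 CPM), and Adamts16, a secreted metalloprotease gene, by 4.75 (3.32 ± 1.51 against 89.6 ± 27.7 CPM). Myo18b, Tmc7 and the predicted genes Gm42842 and Gm3739 had log2 fold changes of -4.54, -4.47, -4.86 and -4.43. Notch4, a Notch receptor, had the lowest log2 fold change of the rule, -6.25 ± 1.53, but 1 library set it, with 1425 CPM in GFP negative replicate 2 against 32.3 and 33.4 CPM in the other 2, and it was -2.33 without that library. These 10 came from 877 lower genes that met the rule, and 9 of them, all but Notch4, passed in each of the 6 fits that left out 1 library. Notch4 lost the call without GFP positive replicate 1, 2 or 3.

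The largest rises included receptors of innate immune cells. Tlr8, a receptor for single-stranded RNA, rose by 3.09 on the log2 scale (128 ± 23.2 against 15.5 ± 20.3 CPM, adjusted p = 0.0449). Ms4a4a, a four-span membrane protein gene of macrophages, rose by 3.11 (49.6 ± 8.91 against 5.94 ± 6.24 CPM), Gpnmb, a glycoprotein gene of lipid-laden macrophages, by 3.21 (43.1 ± 11.5 against 4.90 ± 5.95 CPM), and Clec2i, a C-type lectin, by 3.15 (36.6 ± 5.12 against 4.27 ± 3.98 CPM). Ms4a4b, which has close copies, rose by 3.21, Fam110b by 3.31, Arhgap6 by 3.20, 1700071M16Rik by 3.20, and the predicted genes Gm17230 and Gm15568 by 3.36 and 3.33. The 10 came from 804 qualifying genes. GFP negative replicate 2 was the highest of its group for each of them, for Tlr8 at 38.8 CPM against 4.26 and 3.26 CPM, and without it their log2 fold changes were 4.21 to 5.21. Clec2i and Gm15568 passed in each of the 6 fits that left out 1 library. The other 8 lost the call in at least 1, always including the fit without GFP positive replicate 1, and of these Tlr8, Gpnmb and Fam110b passed only without GFP negative replicate 2.

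Homeostatic microglia genes, which mark the resting resident cell, fell as a group. Of 39 tested, 0 rose and 31 fell, with a median log2 fold change of -1.34, and adjusted over the list alone 33 fell. Adgrg1, an adhesion receptor, fell by 3.70 (61.7 ± 13.1 against 803 ± 74.1 CPM), Ecscr by 4.03, Jam2, a junctional adhesion molecule, by 3.60, and Lag3 by 2.78. Among members chosen after their values were seen, Tmem119 fell by 1.77 (373 ± 64.2 against 1270 ± 344 CPM). Cst3, which encodes cystatin C and was chosen in the same way, fell by 1.74 (863 ± 115 against 2882 ± 1260 CPM). GFP negative replicate 2 held Cst3 at 4332 CPM, against 2099 and 2214 CPM in GFP negative replicates 1 and 3. Without that library the log2 fold change of Cst3 was -1.32. The list was lower by camera (adjusted p = 5e-21), adjusted p = 0.31 with an estimated correlation, and fry gave adjusted p = 0.0015. The count of falls was 22 without GFP positive replicate 1 and 34 without GFP negative replicate 2.

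Genes reported for peripheral macrophages that enter the brain were higher, with 17 of 39 risen and 0 fallen and a median of 2.59. Adjusted over the list alone 32 rose and 1 fell. The list may include genes the study chose on these samples, so none of its counts, its median or its list tests is independent evidence. The same limit holds for members that other lists share with it. Ms4a6b rose by 1.55 (243 ± 39.4 against 82.8 ± 16 CPM), Ms4a6c by 2.71 and Tmem176b by 1.51. Lyz1, a close copy of Lyz2, also rose, at 2.79 ± 0.14 against 0.15 ± 0.13 CPM. Its GFP negative mean lay under the 0.2 to 0.35 CPM that 3 counts correspond to in those libraries. Several abundant members missed the threshold. Apoe, an apolipoprotein of lipid transport, was at 3606 ± 816 against 499 ± 647 CPM (adjusted p = 0.0636), and Cd74, the invariant chain of MHC class II, at 6168 ± 2770 against 1042 ± 1300 CPM (adjusted p = 0.0875). Chosen after their values were seen, Ms4a7 was at 671 ± 123 against 68.1 ± 95.7 CPM (adjusted p = 0.0602), Clec12a at 550 ± 68.8 against 65.1 ± 99.8 CPM (adjusted p = 0.113) and the integrin gene Itga4 at 508 ± 8.41 against 69.3 ± 96.1 CPM (adjusted p = 0.0798). The list was higher by camera (adjusted p = 3.7e-12), and adjusted p = 0.66 with an estimated correlation. With GFP negative replicate 2 left out, 35 members rose, with Apoe at a log2 fold change of 4.84 (adjusted p = 2.92e-07) and Ms4a7 at 5.68 (adjusted p = 2.35e-07), and without any 1 of the other 5 libraries 4 to 9 rose.

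**Figure D2:**
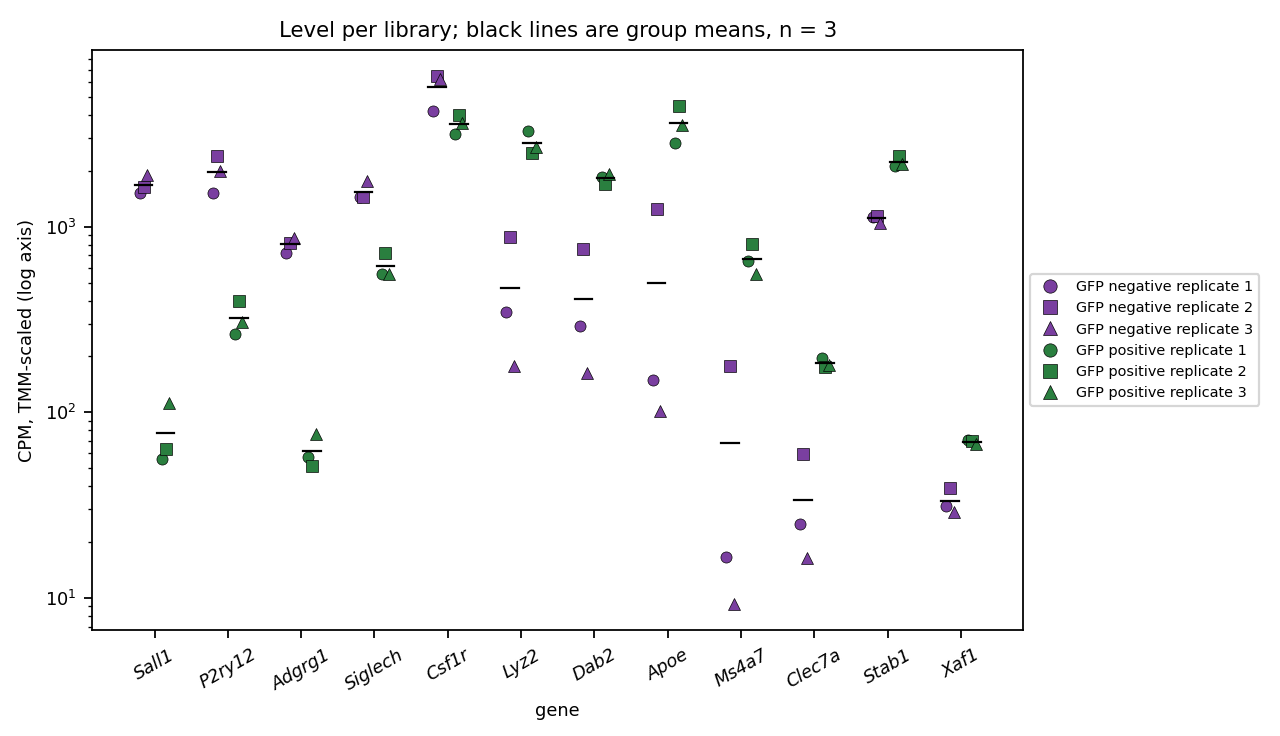
Each symbol is the TMM-scaled CPM of a gene in 1 library on a log axis, with GFP negative in purple, GFP positive in green and group means (n = 3) as black lines. Lyz2, Dab2, Apoe, Ms4a7 and Clec7a were higher in GFP negative replicate 2 (purple squares) than in the other GFP negative libraries, and the Sall1, P2ry12 and Adgrg1 levels of that library lay near those of its group.

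Genes of border-associated macrophages, the macrophages of the meninges and vessel surroundings, were also higher, with 12 of 20 risen, 0 fallen and a median of 1.41. Stab1, a scavenger receptor, rose by 1.01 ± 0.12 (2239 ± 145 against 1109 ± 48.8 CPM), Dab2, an endocytic adaptor, by 2.17 (1827 ± 117 against 406 ± 314 CPM), Pf4, a chemokine, by 2.10, and Cp, which encodes ceruloplasmin, by 2.36. Mrc1, the mannose receptor and a member chosen after its value was seen, rose by 2.36 (1436 ± 113 against 281 ± 239 CPM). A count of members adjusted over the list alone found that 15 rose and 1 fell. The list test gave adjusted p = 5.9e-06, and adjusted p = 0.66 with an estimated correlation. Without GFP negative replicate 2, 14 rose, and without any 1 of the other 5 libraries 1 to 7 did, with Stab1 passing in all 6 of these fits and Dab2 in 2.

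Monocyte genes had a median of 2.15, and 3 of 24 rose and 0 fell. These were Lyz2 by 2.59, Ccr2, the receptor that draws monocytes out of marrow, by 2.03 (71.9 ± 29.9 against 17.8 ± 14.9 CPM), and F13a1, a coagulation factor gene, by 1.74. Nr4a1, the second most abundant member, was at 780 ± 169 against 452 ± 115 CPM (adjusted p = 0.0510). By the count adjusted over the list alone, 20 rose and 0 fell, and the list test gave adjusted p = 6.4e-08, but adjusted p = 0.66 with an estimated correlation. Once GFP negative replicate 2 was left out, 23 of 25 rose, and without any 1 of the other 5 libraries 0 to 4 did.

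Markers of other blood cells were measured because a CD11b isolation can retain them. Of 20 neutrophil genes 2 rose, Padi4 by 2.62 and Il1r2 by 1.42, and Csf3r fell, with a list median of 2.21. The counts adjusted over the list alone were also 2 and 1. The abundant granule gene Ngp was at 805 ± 478 against 153 ± 191 CPM (adjusted p = 0.124), and S100a9, chosen after its value was seen, was at 275 ± 153 against 67.2 ± 95.5 CPM (adjusted p = 0.234). The list test gave adjusted p = 8.2e-05, and adjusted p = 0.66 with an estimated correlation. Without GFP negative replicate 2, 17 rose and 1 fell, and without any 1 of the other 5 libraries 0 to 2 rose. Of 17 dendritic cell genes 2 rose, Clec9a by 2.26 and Kit by 2.30, and 2 fell, Fscn1 by 3.25 (29.8 ± 10.7 against 284 ± 40.5 CPM) and Itgae by 1.29 (list adjusted p = 0.21). Adjusted over the list alone 7 rose and 2 fell, and without GFP negative replicate 2 the counts were 9 and 2, and 0 to 4 rose and 1 to 2 fell without any 1 of the other 5 libraries. Of 13 T and NK cell genes 0 rose and 0 fell, also when adjusted over the list alone (list adjusted p = 0.068), and 9 of 17 rose without GFP negative replicate 2 and 0 to 1 without any 1 of the other 5 libraries. Of 10 B cell genes 0 rose and 1 fell, Ighd by 0.94, with 2 and 2 adjusted over the list alone (list adjusted p = 0.47) and 3 and 2 without GFP negative replicate 2, and 0 to 1 rose without any 1 of the other 5 libraries. Alas2 was the 1 erythroid gene tested, at 8.91 ± 1.93 against 7.41 ± 4.71 CPM (adjusted p = 0.768).

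With all 6 libraries, none of the 5 lists that mark non-immune brain cells passed its test. Of 16 neuron genes 0 rose and 1 fell, Rbfox3 by 1.38 (list adjusted p = 0.47), and 0 and 0 adjusted over the list alone. Of 15 astrocyte genes S1pr1, a lipid receptor, rose (102 ± 25.1 against 50.9 ± 11.4 CPM) and Slc1a3, a glutamate transporter gene, fell by 3.06 (18.4 ± 7.20 against 153 ± 39.8 CPM; list adjusted p = 0.87), with the counts adjusted over the list alone also 1 and 1. Of 15 oligodendrocyte genes 0 rose and 0 fell by either count (list adjusted p = 0.70), and Mbp, which encodes myelin basic protein, was at 352 ± 142 against 321 ± 104 CPM. Of 19 endothelial and mural genes 0 rose and 3 fell, Pecam1 by 1.92, Kdr by 1.80 and Pdgfrb from 7.86 ± 2.55 to 2.77 ± 0.26 CPM (list adjusted p = 0.62), with 1 and 3 adjusted over the list alone. Of 7 choroid plexus and ependymal genes 0 rose and 0 fell by either count (list adjusted p = 0.70). The astrocyte list had 3 rises and 1 fall without GFP negative replicate 2, the neuron list 1 and 1, the oligodendrocyte list 1 and 0 and the endothelial list 2 and 3, and 1 to 2 endothelial genes fell without any 1 of the other 5 libraries.

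Interferon response genes were higher across most of their list. Of 33 type I interferon response genes 24 rose and 0 fell, with a median of 1.06. Mx1 and Mx2, antiviral GTPases, rose by 1.26 (54.5 ± 7.90 against 22.7 ± 3.76 CPM) and 0.94, Xaf1 by 1.06 (69.3 ± 1.53 against 33.2 ± 5.32 CPM) and Parp14 by 0.87 (307 ± 22.9 against 169 ± 19.4 CPM). Oasl2, chosen after its value was seen, rose by 1.84 (301 ± 25.5 against 84.2 ± 52.1 CPM). When adjusted over the list alone, 27 rose. The list test gave adjusted p = 5.9e-12, and adjusted p = 0.66 with an estimated correlation. Without GFP negative replicate 2, 27 rose, without any 1 of the other 5 libraries 8 to 15 did, and the 4 named by the rule passed in all 6 fits.

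Antigen presentation genes followed with smaller counts. Of 21 MHC class I genes 9 rose and 0 fell, with a median of 0.59. Nlrc5, the transactivator of class I genes, rose by 1.78 (192 ± 14 against 56.0 ± 14.9 CPM), H2-K1 by 1.01 (781 ± 103 against 388 ± 70.1 CPM), and the near-identical H2-Q6 and H2-Q7 by 1.46 and 1.41. The list test gave adjusted p = 0.00038, and adjusted p = 0.66 with an estimated correlation, and 10 rose adjusted over the list alone. Once GFP negative replicate 2 was left out, 11 rose, and without any 1 of the other 5 libraries 4 to 7 did. Of 15 MHC class II genes 3 rose and 0 fell, with a median of 0.94. These were the costimulatory receptor genes Cd86 by 0.94 (549 ± 93.5 against 286 ± 42.5 CPM) and Cd40 by 2.07, and H2-DMb2 by 1.06. H2-Aa, chosen after its value was seen, was at 1235 ± 520 against 189 ± 280 CPM (adjusted p = 0.151). With adjustment of p restricted to its members (adjusted over the list alone), 5 rose and 1 fell. The class II list test gave adjusted p = 0.0016, and adjusted p = 0.66 with an estimated correlation. Without GFP negative replicate 2, 11 class II genes rose and 1 fell, and without any 1 of the other 5 libraries 0 to 2 rose.

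Inflammatory genes moved in both directions. Of 22 NF-kB and cytokine genes 9 rose and 1 fell. Il1b, a pyrogenic cytokine, rose by 1.96 (1010 ± 214 against 260 ± 140 CPM), Nfkbiz by 1.05 and Cxcl10 by 0.93, and Il1a fell by 1.04 (270 ± 48.6 against 557 ± 32.4 CPM). Camera gave this list adjusted p = 0.0016, and adjusted p = 0.66 with an estimated correlation, and 12 rose and 2 fell adjusted over the list alone. Of 30 chemokine and chemokine receptor genes 8 rose and 1 fell. Ccl7 rose by 1.69, Ccl12 by 1.20 and C3ar1, the receptor for complement C3a, by 0.75 (509 ± 46.0 against 303 ± 38.0 CPM). A count of members adjusted over the list alone found that 17 rose and 2 fell. The chemokine list test gave adjusted p = 0.00042, and adjusted p = 0.66 with an estimated correlation. With GFP negative replicate 2 left out, 13 cytokine and 20 chemokine genes rose and 2 of each fell, and without any 1 of the other 5 libraries 1 to 8 and 2 to 7 rose.

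Families of surface receptors were counted in the same way. Of 12 membrane-spanning 4A genes, some of them also in the peripheral macrophage list and under its limit, 7 rose and 0 fell, with a median of 2.75. Adjusted over the list alone 10 rose. Its test gave adjusted p = 9.1e-07, and adjusted p = 0.66 with an estimated correlation, and 12 of 13 rose without GFP negative replicate 2 and 3 to 5 without any 1 of the other 5 libraries. Of 26 C-type lectin and Siglec genes 8 rose and 2 fell. Clec7a, the beta-glucan receptor dectin-1, rose by 2.46 (184 ± 11.3 against 33.7 ± 23 CPM) and Clec2d by 1.76, and Siglech fell by 1.34 (613 ± 95.3 against 1548 ± 178 CPM) and Siglecf by 2.84. The lectin list test gave adjusted p = 0.0037, and adjusted p = 0.66 with an estimated correlation. By the count adjusted over the list alone, 15 rose and 3 fell, and without GFP negative replicate 2 the counts were 17 and 2, and 2 to 5 rose without any 1 of the other 5 libraries. Of 26 pattern recognition receptors 6 rose, among them Tlr2 by 1.29 (327 ± 38.2 against 134 ± 26.4 CPM), and 3 fell, among them Tlr3, a sensor of double-stranded RNA, by 1.82 (59.4 ± 5.68 against 210 ± 54.7 CPM) and Tlr5 by 0.64 (list adjusted p = 0.47). Adjusted over the list alone 8 rose and 6 fell, and without GFP negative replicate 2 the counts were 9 and 5, and 2 to 3 rose and 1 to 5 fell without any 1 of the other 5 libraries. Of 20 complement and Fc receptor genes 5 rose, among them Fcgr4 by 1.44, and 3 fell, among them Fcgr3 by 0.87. These counts were also 5 and 3 adjusted over the list alone (list adjusted p = 0.87), and the list median of -0.0756 and mean of 0.159 differed in sign. With GFP negative replicate 2 left out, 6 rose and 3 fell, and 0 to 3 rose and 1 to 3 fell without any 1 of the other 5 libraries. C1qb, chosen after its value was seen, was at 805 ± 125 against 1166 ± 354 CPM (adjusted p = 0.171).

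Purinergic, adhesion and TGF-beta genes had more falls than rises. Of 18 purinergic genes 2 rose and 6 fell. P2ry12, an ADP receptor of microglial processes, fell by 2.61 ± 0.22 (323 ± 66.9 against 1970 ± 442 CPM), Adora3, an adenosine receptor, by 3.30, P2ry13 by 1.20 and Entpd1, which breaks down extracellular ATP, by 1.11 (list adjusted p = 0.47). When adjusted over the list alone, 6 rose and 6 fell, the median of -0.337 and the mean of 0.0158 differed in sign, and without GFP negative replicate 2 the counts were 7 and 6, and 0 to 2 rose and 3 to 5 fell without any 1 of the other 5 libraries. Of 31 integrin and adhesion genes 2 rose and 9 fell. Selplg, a selectin ligand, fell by 2.87 (150.0 ± 37 against 1099 ± 152 CPM), Itgb3 by 2.89 and the tetraspanin gene Cd81 by 1.18 (list adjusted p = 0.48). Adjusted over the list alone 8 rose and 10 fell, camera gave the direction down although the median was 0.0714, and without GFP negative replicate 2 the counts were 10 and 12, and 1 rose and 5 to 7 fell without any 1 of the other 5 libraries. Of 22 TGF-beta genes 2 rose, among them Pmepa1 by 1.35 (1669 ± 323 against 655 ± 32.0 CPM), and 5 fell, among them Eng, a co-receptor, by 2.29, Smad7 by 1.01 and Tgfb1 by 0.85 (list adjusted p = 0.93). A count of members adjusted over the list alone found that 3 rose and 5 fell, and without GFP negative replicate 2 the counts were 6 and 6, and 1 to 2 rose and 2 to 4 fell without any 1 of the other 5 libraries. Of 34 transcription factors of macrophage identity 2 rose and 4 fell, Sall1, Sall3, Meis1 by 1.47 and Ikzf1 by 0.61 (list adjusted p = 0.66). By the count adjusted over the list alone, 3 rose and 4 fell, the median of -0.138 and the mean of 0.0047 differed in sign, and without GFP negative replicate 2 9 of 35 rose and 6 fell, and 0 to 2 rose and 2 to 3 fell without any 1 of the other 5 libraries.

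Lipid, lysosomal and disease-associated genes were higher in part. Of 30 lipid and cholesterol genes 11 rose and 0 fell, with a median of 0.80. Plin2, a lipid droplet coat protein, rose by 2.02 (114 ± 15.1 against 28.1 ± 10.7 CPM), Apobec1 by 2.16 (985 ± 176 against 221 ± 129 CPM), Pltp by 1.54 and Abca1, a cholesterol exporter, by 0.88 (1690 ± 254 against 917 ± 61.9 CPM). All 4 passed in each of the 6 fits that left out 1 library. Camera gave this list adjusted p = 0.00038, and adjusted p = 0.66 with an estimated correlation. With adjustment of p restricted to its members (adjusted over the list alone), 14 rose and 1 fell, and the counts were 16 and 2 without GFP negative replicate 2, and 5 to 9 rose without any 1 of the other 5 libraries. Of 33 lysosomal genes 6 rose and 1 fell, with Ctsc, the cathepsin that activates granule proteases, up by 1.57 (1199 ± 42.8 against 404 ± 122 CPM), Gla by 1.11 and Cd63 by 1.28. The lysosomal list test gave adjusted p = 0.13, and 8 rose and 3 fell adjusted over the list alone. Once GFP negative replicate 2 was left out, 11 rose and 3 fell and that test passed (list adjusted p = 0.044, and adjusted p = 0.54 with an estimated correlation), and 3 to 4 rose without any 1 of the other 5 libraries. Of 28 disease-associated microglia genes 10 rose, with Clec7a and Lyz2 among the smallest p, and 2 fell, Csf1 by 2.87 and Cd9 by 1.21. Camera gave this list adjusted p = 0.014, and adjusted p = 0.69 with an estimated correlation. When adjusted over the list alone, 13 rose and 4 fell, and without GFP negative replicate 2 16 rose and 4 fell, against 3 to 4 rises without any 1 of the other 5 libraries.

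**Figure D3:**
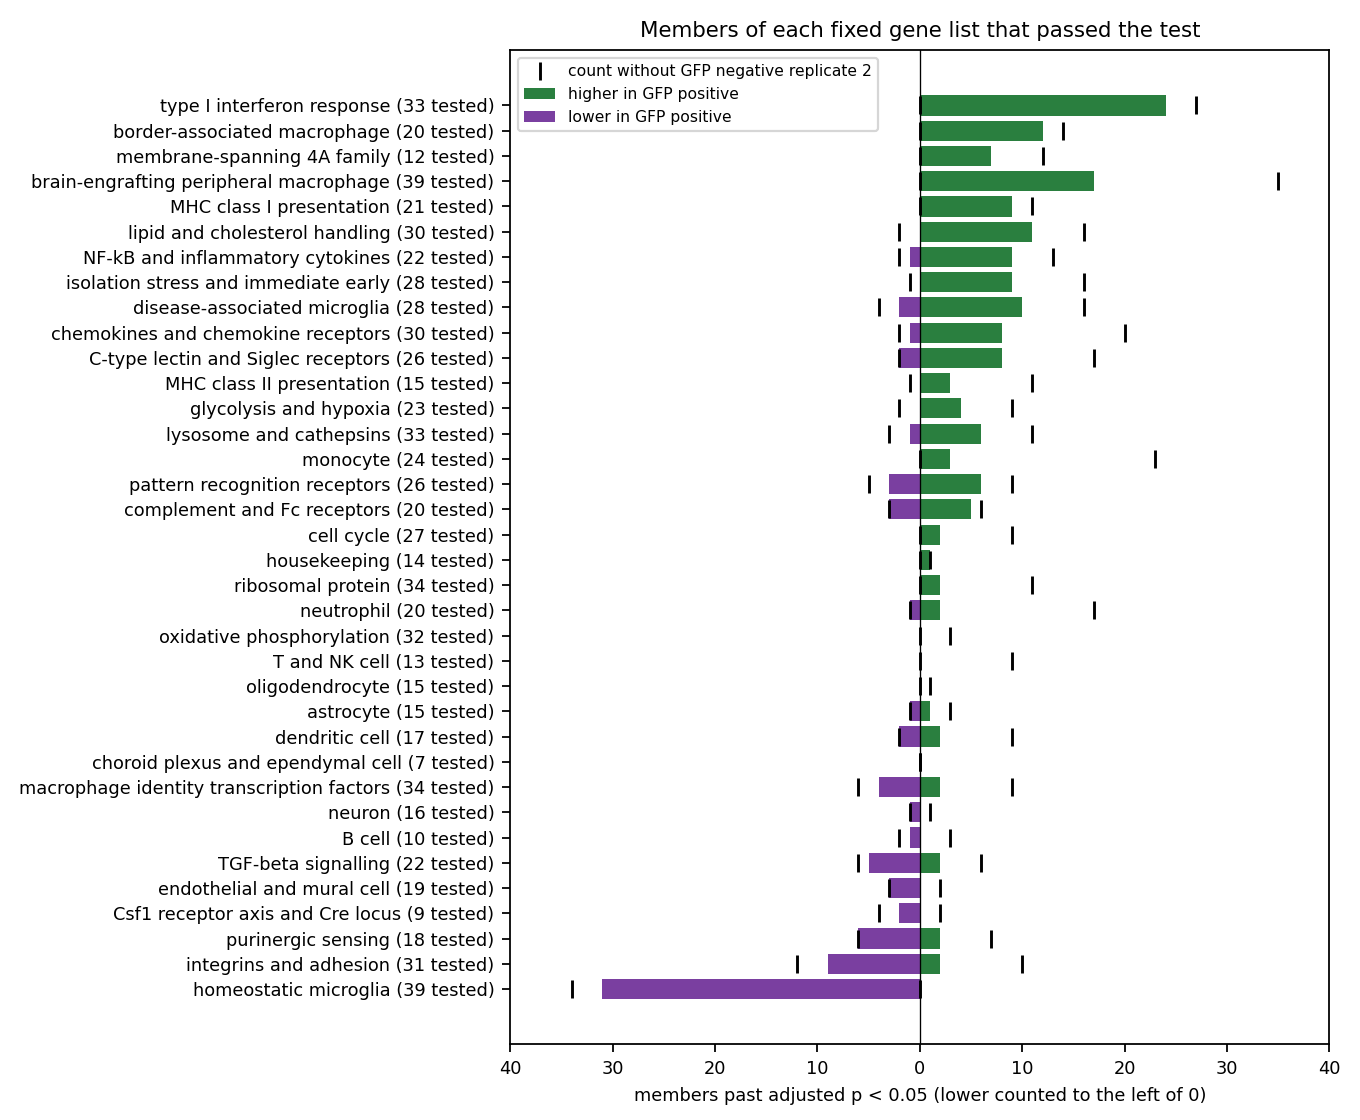
Bars count the members of each fixed list past the threshold, with higher genes to the right of 0 and lower genes to the left, and black ticks give the same counts without GFP negative replicate 2. The homeostatic microglia bar reaches 31 of 39 on the left, and the type I interferon bar reaches 24 of 33 on the right.

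Lists of cell state and of handling were also examined. Of 28 immediate early and isolation stress genes 9 rose and 0 fell, with Fos up by 1.19 (639 ± 129 against 280 ± 41.1 CPM) and the near-identical heat shock genes Hspa1a (883 ± 144 against 440.4 ± 89.7 CPM) and Hspa1b (284 ± 17.1 against 143 ± 22.9 CPM) also higher. Its test gave adjusted p = 0.00067, and adjusted p = 0.66 with an estimated correlation. Adjusted over the list alone 15 rose and 1 fell, and 16 rose and 1 fell without GFP negative replicate 2, against 3 to 10 rises without any 1 of the other 5 libraries. Of 27 cell cycle genes 2 rose, the mitotic motor gene Kif11 by 2.29 (12.5 ± 6.60 against 2.59 ± 1.38 CPM) and Mcm6 by 0.80, and 0 fell, with list adjusted p = 0.0049, and adjusted p = 0.66 with an estimated correlation. A count of members adjusted over the list alone found that 5 rose, and 9 did without GFP negative replicate 2, against 0 to 2 without any 1 of the other 5 libraries. Of 23 glycolysis and hypoxia genes 4 rose and 0 fell, Vegfa, the vascular growth factor gene, by 2.28 (63.0 ± 4.56 against 13.2 ± 11.9 CPM), Slc2a3 by 1.77, Ndrg1 (11.4 ± 4.40 against 2.85 ± 0.19 CPM) and Pgk1 by 1.01. The list gave adjusted p = 0.044, and adjusted p = 0.66 with an estimated correlation, with 6 risen adjusted over the list alone, and 9 risen and 2 fallen without GFP negative replicate 2, against 0 to 2 risen without any 1 of the other 5 libraries. Of 34 ribosomal protein genes 2 rose, Rps16 by 1.08 and Rpl32 by 0.82, and 0 fell, with a median of 0.29, list adjusted p = 0.0058, and adjusted p = 0.69 with an estimated correlation. By the count adjusted over the list alone, 1 rose, and 11 did without GFP negative replicate 2, against 0 to 1 without any 1 of the other 5 libraries. Of 32 oxidative phosphorylation genes 0 rose and 0 fell by either count (list adjusted p = 0.39), and 3 rose without GFP negative replicate 2. Of 14 housekeeping genes Pgk1 rose and 0 fell by either count (list adjusted p = 0.50), and the list median of -0.0704 and mean of 0.0944 differed in sign.

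Over all 36 lists, camera with the preset correlation called 17 higher and 1 lower. With an estimated correlation 0 were called, 1 having an unadjusted p under 0.05, and the lowest adjusted p was 0.31. The fry test called 1 list in one direction, homeostatic microglia, and 28 lists for change in either direction. Some calls of the preset camera test changed with 1 library left out. Without GFP negative replicate 2 the test passed as higher for dendritic cell (adjusted p = 0.027), T and NK cell (0.0013), neuron (0.018), lysosomal (0.044) and oxidative phosphorylation genes (0.047), and it no longer passed for glycolysis and hypoxia genes (0.052). With an estimated correlation 0 lists were called in that fit, where the lowest adjusted p was 0.24. Glycolysis and hypoxia also missed without GFP positive replicate 1 or 3 or GFP negative replicate 1, ribosomal protein without GFP positive replicate 3 or GFP negative replicate 1 or 3, and cell cycle and disease-associated microglia without GFP negative replicate 1. The T and NK cell list also passed without GFP negative replicate 1 or 3, and the Csf1 receptor axis list without GFP negative replicate 1.

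Leaving out GFP negative replicate 2 ended no call among the named genes, and leaving out another library ended many. Many rises were larger without GFP negative replicate 2, with log2 fold changes of 3.81 for Padi4, 3.42 for Lyz2, 3.29 for Vegfa, 3.18 for Cp, 3.30 for Mrc1, 3.14 for Clec9a and Clec7a, 2.99 for Kit, 2.97 for Ccr2 and 2.75 for Apobec1. Among the 6 fits that each left out 1 library, Il1b, Nfkbiz, Cp, Lyz1, Lyz2, C3ar1, Cd86, Csf3r, Itgae, Ndrg1, Oasl2, P2ry13 and Tgfb1 lost the call only without GFP positive replicate 1. Ccl7, Pf4 and Rps16 lost it without GFP positive replicate 1 or 3, Fcgr3 without GFP positive replicate 1 or GFP negative replicate 3, and Meis1 without GFP positive replicate 3 or GFP negative replicate 1. The rises of Ccr2, Cd40, Cd63, Clec9a, Dab2, Fcgr4, Il1r2, Kif11, Kit, Mrc1, Padi4, S1pr1 and Slc2a3 and the falls of Pecam1 and Tlr5 passed in 2 of the 6 fits. F13a1, H2-DMb2, Mcm6, Pgk1, Rpl32, Vegfa, Ikzf1, Pdgfrb and Rbfox3 passed in 1, and Ighd and Siglecf in 3.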

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

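The counts without GFP negative replicate 2 for list members were chosen after that library was seen. With the edgeR quasi-likelihood test, the count of 2262 genes (1070 higher, 1192 lower) stayed within 1.5 times under the 3 other scalings, DESeq2 (3209), limma-voom (2915) and both other filters. It was 900 (337 higher, 563 lower) with glmTreat, which asks for more than a 1.5-fold change, and all 900 were among the 2262. Leaving out 1 library gave 819 to 4317 genes, 294 to 2342 higher and 525 to 1975 lower, with fewer samples in each fit, and 0 of the 2262 changed sign in any alternative. The values gave no sign that the replicate numbers pair the samples: deviations from the group means of same-numbered libraries correlated at 0.029, -0.29 and -0.16 across genes, and 1 of 6 libraries correlated best with its own number. Deviations from a mean of 3 libraries sum to 0, and GFP negative replicate 2 dominates those of its group. This check therefore had little power and leaves pairing open. With the replicate block 1298 genes passed (558 higher, 740 lower), 1271 of them among the 2262.

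Csf1r, at adjusted p = 0.0515, passed with upper-quartile scaling (log2 fold change -0.66, adjusted p = 0.0481), DESeq2 (-0.65, adjusted p = 0.0144), limma-voom (-0.62, adjusted p = 0.0253) and no filter (-0.61, adjusted p = 0.0427). With 1 library left out it ran from -0.82 to -0.54 and Cx3cr1 from -0.64 to -0.07. The cause of these differences was not tested. For 144 genes chosen by rule or for the text, 2157 gene and setting pairs gave 1856 on the same side of the threshold, 255 that lost it, 41 that gained it and 5 with another sign. The reversed values were Camk2a without GFP positive replicate 3, GFP negative replicate 1 and GFP negative replicate 3, in a range of -0.0797 to 0.52 with 1 library left out, and Mbp at -0.19 without GFP positive replicate 3 and -0.11 without GFP negative replicate 1, in a range of -0.19 to 0.41. Neither gene passed in these fits.

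Lists higher numbered 17, against 0 with an estimated correlation, 0 with fry and 14 to 21 with 1 library left out. Lists lower numbered 1, against 0 with an estimated correlation and 1 to 2 with 1 library left out. Some lists took the other direction, at these adjusted p and without passing there. With fry they were astrocyte (0.99) and TGF-beta (0.71), and with the replicate block complement and Fc receptors (0.97). With 1 library left out, such lists ranged over all 6 fits from 0.018 to 0.96 for neuron, which passed as higher without GFP negative replicate 2, 0.33 to 0.98 for astrocyte, with 0.46, 0.73 and 0.92 among the others, 0.2 to 0.78 for oligodendrocyte, 0.34 to 0.99 for endothelial, 0.44 to 0.94 for choroid plexus, 0.52 to 0.94 for complement and Fc receptors, 0.64 to 0.99 for TGF-beta, 0.39 to 0.92 for transcription factors and 0.27 to 0.97 for integrins. The cause was not tested. Simulated 2-fold changes were recovered for 10 of 50 genes. The simulation made 172 calls against 2262 in the data, so the unadjusted p needed to pass was lower in the simulation. Changes of that size can be missed in the data, but the simulation does not tell how many.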

Other observations

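Tests on mixing, wrong label and carry-over were chosen after the results were seen, as were the genes in the next paragraph, whereas those on depth, other cell types, RNA without poly(A) tails and other splits were set beforehand.

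Outside every fixed list, the most abundant named genes with at least 4-fold differences included cytoskeletal and signalling genes. Among 192 such higher genes, Myo5a, an actin motor, rose by 2.64 on the log2 scale (1449 ± 163 against 233 ± 210 CPM), Iqgap1, a cytoskeletal scaffold, by 2.38 (985 ± 332 against 190 ± 177 CPM), Trps1, a GATA-type repressor, by 3.01, St8sia4, a polysialyltransferase, by 2.26 (394 ± 7.27 against 82.4 ± 52.4 CPM), Itsn1, an endocytic scaffold, by 2.36, and Arhgap15, a Rac regulator, by 2.61. Among 216 lower genes, Mlxipl, a glucose-responsive transcription factor, fell by 2.78 (146 ± 21 against 1004 ± 163 CPM), Col27a1, a fibrillar collagen gene, by 2.31 (188 ± 24.4 CPM with GFP), and Lrrc3 by 2.11. Adamts1, a secreted protease gene, fell by 3.92, Atp8a2, a lipid flippase, by 3.56, and the growth factor gene Tgfa was lower at 76.0 ± 13.2 against 304 ± 60.8 CPM. The edgeR calls of St8sia4, Arhgap15, Mlxipl, Col27a1, Adamts1, Atp8a2, Tgfa and Lrrc3 held in all 6 fits that left out 1 library. Myo5a lost the call without GFP positive replicate 1, Itsn1 passed in 3 of those fits and Trps1 in 2, and Iqgap1 passed only without GFP negative replicate 2, where its log2 fold change was 3.46 and those of the 5 other rises were 2.91 to 4.38.

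GFP negative replicate 2 held genes high in GFP positive libraries at a level between the groups, at a median share of 32.5% of the way (95% bootstrap interval 31.4 to 33.5%, 824 genes). That share argues against a GFP positive library under the wrong label. The 824 were those of 2342 genes called higher without that library that passed 2 cuts. They rose over 2-fold in that fit and averaged at least 10 CPM over all 6 libraries, GFP negative replicate 2 included. Bootstrap intervals in this section resample genes, which can vary together, so they do not measure the spread between libraries. GFP negative replicate 1 thinned to the same total gave a share of 2.44% (1.87 to 3.16%). A share near 0 was built in, since these genes were called with that replicate low and thinning keeps the expected CPM. The thinned share therefore does not decide on lower depth. Counting noise does not shift the expected CPM, so the 32.5% over 824 genes argues against counting noise as its cause. Other effects of lower depth stay open. RNA of GFP positive type cells mixed in stays open. Of 1975 genes called lower without GFP negative replicate 2, the same cuts on fold and mean CPM left 576. These gave a median of 34.8% (30.2 to 38.3%), with quartiles of 0.413 and 58.5%. Among them were 26 of the 34 homeostatic microglia genes called lower in that fit. The 26 gave 6.13% (-12.3 to 33.3%), an interval that holds both 0 and the share of the higher genes. P2ry12 was at 2398 CPM in that library against 1516 and 1997 CPM in replicates 1 and 3. The 31 homeostatic genes lower with all libraries gave 6.1% (-23.9 to 20.9%), below the share of the higher genes. Their choice used that library and favours genes it held high, so they do not decide. Dilution of an otherwise unaltered GFP negative population stays open too, since the interval of the 26 genes reaches the share of the higher genes. Macrophages without GFP and GFP positive cells carried over in the sort cannot be told apart, because 0 genes in the table mark GFP itself.

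Of the 17378 genes tested, a group of 121 genes stood over 4 times above the highest other library and over 5 CPM in GFP negative replicate 2. Each other library had 0 or 1 such genes. Genes removed by the filter, which could include some seen in that replicate alone, were not searched. Among them, chosen after their values were seen, were Notch4 (1425 against at most 33.4 CPM), the small nuclear RNA gene Rn7sk (1532 against 116 CPM), mt-Nd6 (458 against 17.7 CPM) and Zfp457 (75.4 against 1.08 CPM). Counting noise at lower depth is argued against, since 0 such genes appeared in GFP negative replicate 1 thinned to that total. That replicate had 0 before thinning too, and thinning keeps the expected CPM, so other effects of depth are not covered. A general rise of short RNA without poly(A) tails is argued against, since 240 short noncoding and histone genes had a median log2 ratio of -0.52 (-0.684 to -0.273) over replicates 1 and 3. That set left out Rn7sk and the mitochondrial genes, which were seen first, and also microRNA genes. A rise limited to such RNA therefore stays open. Of the genes tested, the 121 included 3 of 134 microRNA, 2 of 120 small nucleolar RNA and 74 of 13258 protein-coding genes. The 18 histone genes alone, at 0.335 (-0.27 to 0.626), leave histone RNA open. Cells of another brain or vascular type may contribute and stay open. The highest list median log2 ratio was 0.961 (0.713 to 1.22) for neurons, whose most abundant members, Meg3 and Camk2a, were at 86.7 and 65.2 CPM. The endothelial and mural list had 0.286 (-0.123 to 1.09), although its members Tek and Cdh5 were among the 121 genes. How fully the CD11b selection removed such cells was not measured. Apart from these mixtures of cells, no biological explanation was tested for this library.

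Microglial genes that fell kept part of their level in GFP positive cells, a median of 31.8% (18.4 to 40%) of the level in GFP negative replicates 1 and 3 over the 31 fallen homeostatic genes. Carry-over of GFP negative cells gives 1 share to every gene, and 23 of the 31 kept more than 2 times the share of Sall1 in each GFP positive library, which argues against it as the whole cause. Sall1 kept 4.51% (SD 1.76), Sall3 3.37% and Upk1b 4.27%, whereas P2ry12 kept 18.4% and Tmem119 26.3%. Carry-over may be present and stays open, at no more than the lowest share among the 31 genes, 3.37% for Sall3 (SD 2.1). A candidate explanation for the rest, not tested here, is partial expression of these genes in the GFP positive cells themselves.

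The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2262 genes, the highest other split called 0, and 1 split, the real one, gave as many.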
